A study of Homo sapiens with 6 samples.

How the data were processed

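Whole-transcriptome RNA-seq was analysed for 6 libraries of primary human keratinocytes (NHEK, the main cell type of the epidermis) from 1 donor. Per the labels' protocols, the cells were kept in a low-calcium medium with 0.06 mM CaCl2, differentiated for 3 days in 1.3 mM CaCl2, and then given 200 ng/ml of IL-36γ, a cytokine of the IL-1 family made by epithelial cells, for 2 days. Poly(A) libraries were made from 250 ng of total RNA with a KAPA mRNA kit and sequenced as 150 bp paired reads, per the labels. The series text and the sample protocols name different sequencers, and it was not settled here which was used.

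The titles of 3 libraries carry the tag IL36R (replicates 10, 11 and 12), and these form the IL36R group. The titles of the other 3 (replicates 1, 2 and 3) carry no treatment tag, and these form the untagged group. The protocol text is the same for all 6 libraries and the labels do not call the untagged libraries a control. That the tag marks wells given IL-36γ and that the untagged wells went without it are inferences from the titles, so each result below is stated as IL36R against untagged. Replicate numbers were read from the D numbers in the titles, and what these mark is not stated. They are not shared between the groups, so no libraries were paired. They run in separate blocks for the groups, so any order they mark is confounded with the tag. All 6 titles carry the same lane token, and the labels give no other batch. The series text speaks of triplicate culture of cells of 1 donor, so p-values measure the spread between these wells and not between people, and part of that spread may be technical.

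The authors deposited 1 table of raw read counts per gene, with 1 column per library and no normalization. Per the series design text, reads were trimmed with skewer 0.2.2 (end quality 15, mean quality 25, minimum length 30), aligned to GRCh38 with HISAT2 2.1.0 at default settings, and counted with htseq-count 0.9.1 on the Ensembl 84 gene model in reverse-stranded, intersection-nonempty mode with a minimum alignment quality of 20. The counting used the strand, so antisense partners were counted apart. The quality minimum drops reads that map equally well to several places, so genes with near-identical copies (DEFB4A and DEFB4B, DEFB103A and DEFB103B, members of the SPRR2, LCE, KRT6 and S100A7 families, SAA1 and SAA2, SERPINB3 and SERPINB4, HLA genes) may be undercounted and their split between copies is uncertain. Reads that overlap 2 genes on the same strand were assigned only where the mode allowed it.

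The table held 60675 rows, of which 29420 had a count in any library. Every value was a whole number, no row lacked a gene name, and every column matched 1 library. Total counts ran from 21.6 to 30.3 M per library. Row names are gene symbols or Ensembl gene IDs. For locations, transcript length and GC content they were matched to the GENCODE v44 annotation of GRCh38, the same build but a later gene model than the one used for counting: 51006 rows matched by symbol, 4380 by Ensembl ID and 835 through an older symbol, and 4454 did not match. Coordinates below are 1-based gene spans, exons and introns together.

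The comparison was made in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by group (minimum count 10), glmQLFit with robust estimation and glmQLFTest, with group as the only term and a Benjamini-Hochberg adjusted p below 0.05 as the threshold. Of all rows, 15227 genes were tested. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to a common library size with TMM factors. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. The correlation estimated per list, fry, and cameraPR on ranked statistics were run as alternatives. With an estimated correlation camera takes its degrees of freedom from the 6 libraries, and with the preset one from the number of genes. The former is thus the weaker test, also where the estimate is near 0. Camera asks whether the signed changes of a list were on average higher or lower than those of other genes. Fry asks whether the members moved on balance in 1 direction. A list with many members changed both ways can thus go uncalled by either. Single values per library were compared with a two-sided exact permutation test of the mean. With 3 libraries against 3 its smallest p is 0.1, so it cannot pass 0.05. Intervals on counts are 95% intervals, exact binomial for the ratios of single genes and a normal approximation for summed markers of other cell types. The approximation is rough at low counts. Both pool the 3 libraries of a group, so they cover counting error only and not the spread between wells. The reads carry no molecular identifiers.

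The genes named were fixed by rule before the data were examined, and 2 list members that the rule chose are left out of the text. The rule takes the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 2 CPM and no overlap between the groups, leaving out clone-based names. It adds 23 fixed genes whatever their result, and of each of 29 fixed lists up to 4 called members with the smallest p, with every tested member of the lists for other cell types. Rows known only by an Ensembl ID were left out of the first part. Further list members named below were chosen after their values were seen. The lists cover IL-1 family, chemokine, NF-κB, antimicrobial, complement, interferon, virus sensing, MHC class I, type 2, differentiation, cornified envelope, barrier lipid, cholesterol, basal, wound, protease, serpin, junction, cell cycle, hypoxia, oxidative stress, unfolded protein, retinoid and housekeeping genes, and markers of melanocytes, fibroblasts, immune cells, and endothelial and Merkel cells. A further 3 lists and 3 gene families, described in the closing part, were chosen after the data were seen.

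The scripts were tested on counts simulated from the means and library sizes of these samples over 15227 genes, with 50 genes changed at each of 4 sizes. The test called 64% of genes changed 1.2-fold, 78% at 1.5-fold, 92% at 2-fold and 100% at 4-fold, with 3 false calls among 170, and it called both changed sets and 0 of 27 unchanged ones. Each gene was drawn independently, at the variation given by the trend over expression and with none of its own, and few genes were changed. Genes whose variation departs from the trend may be recovered less well. The simulation therefore does not show how often camera falsely calls lists of correlated genes, or how the tests behave where many genes change. Alternatives set before the data were examined were DESeq2 size factors, upper-quartile factors or total counts in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom, other filters on low counts, leaving out each library, leaving out mitochondrial genes, estimation without robust weights, an adjusted p below 0.01 and a test against a 1.5-fold change. Removal of GC and transcript length trends and thinning to equal totals were added later. Figures were drawn with matplotlib 3.10.9.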

Results

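The data were gene counts from 6 RNA-seq libraries of calcium-differentiated keratinocytes of 1 donor, 3 in the IL36R group and 3 in the untagged group. Total counts were 25.0, 21.6 and 27.4 M in IL36R replicates 10, 11 and 12 and 30.3, 27.1 and 25.1 M in untagged replicates 1, 2 and 3. The group means, 24.7 ± 2.94 M and 27.5 ± 2.60 M (SD, n = 3 each), did not differ by more than the spread between libraries (two-sided exact permutation p = 0.40, the smallest possible being 0.1). Between 22492 and 23657 rows had a count in each library. Pairs of libraries within a group correlated at r = 0.9947 to 0.9954 across genes, and pairs from different groups at 0.9833 to 0.9853. Within-group pairs still differed by more than counting noise, with a chi-square per gene of 2.63 to 6.81, so no library was counted as a duplicate of another. The first principal component held 65.0% of the variance and the second 9.8%.

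The comparison asks which transcripts of differentiated keratinocytes differ between wells labelled for the IL-36 receptor axis and wells without that tag. In the IL36R libraries, transcripts of the cytokine IL1B, the chemokines CXCL1 and CXCL8 and most tested genes for antimicrobial proteins, small proline-rich proteins and cholesterol synthesis were higher. Loricrin, keratin 10, the growth factor binding protein IGFBP3 and most tested basal keratinocyte genes were lower. The calls of these lists were lost with an estimated correlation (camera adjusted p = 0.16, 0.16, 0.17 and 0.17). The estimate was above the preset 0.01 for antimicrobial (0.043) and cholesterol synthesis genes (0.20). It was below 0.01 for small proline-rich (-0.017) and basal keratinocyte genes (0.0075), so correlation between members does not account for every loss. In all, 3799 genes were higher and 3629 lower, together 7428 of 15227 tested genes (48.8%; edgeR quasi-likelihood test, adjusted p below 0.05). The wells came from 1 donor, and what separates tagged from untagged wells is read only from the titles. Gene values in brackets are log2 fold changes ± SE from edgeR, and CPM values are mean ± SD, IL36R first (n = 3 each). Most changes were small. Of the called genes 5667 (76.3%) changed by less than 1.5-fold and the median absolute log2 fold change was 0.33, while 350 genes were at least 2-fold higher and 223 at least 2-fold lower. With a filter of at least 1 CPM in at least 3 libraries the latter counts were 233 and 129. The groups did not overlap for 8491 tested genes (55.8%), where chance gives 10% for 3 against 3. Tested against a 1.5-fold change, 392 genes were higher and 182 lower.

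**Figure D1:**
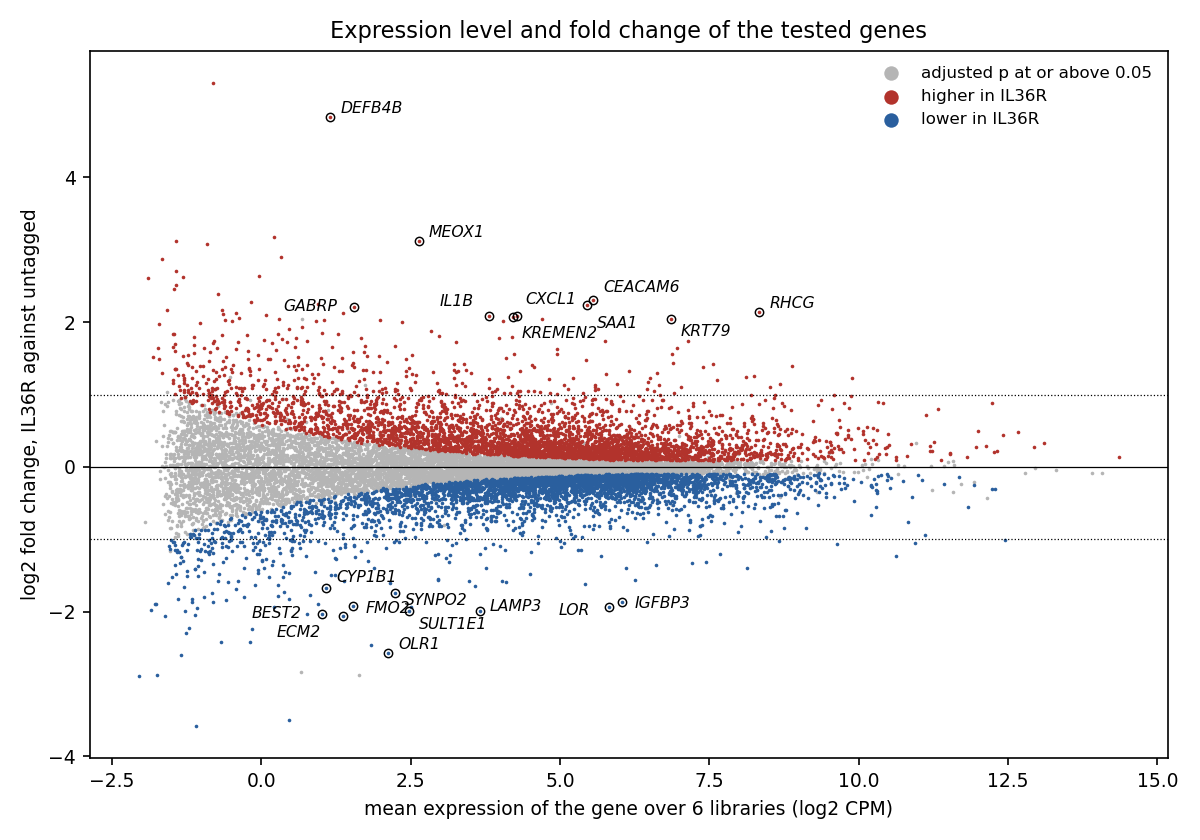
Log2 fold change of the tested genes (IL36R against untagged, vertical axis) against their mean log2 CPM over the 6 libraries (horizontal axis). Red points were higher and blue points lower in IL36R at an edgeR adjusted p below 0.05, grey points were not called, dotted lines mark 2-fold, and circles mark the 10 highest and 10 lowest genes chosen by rule; most of the 3799 higher and 3629 lower genes lie between the dotted lines.

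Among the called genes with a mean of at least 2 CPM and no overlap between the groups, the largest rise was that of DEFB4B (chromosome 8, 7414855 to 7416863 on GRCh38), which encodes the antimicrobial peptide β-defensin 2, at 28.5-fold (4.83 ± 0.30, edgeR adjusted p = 1.6e-13). It rested on 309 counts in the IL36R libraries and 12 in the untagged ones, a depth-scaled ratio of 29.2 with a 95% counting interval of 16.5 to 57.0. Its near-identical copy DEFB4A (chromosome 8, 7894677 to 7896716) rose 39.6-fold (5.31 ± 0.60, edgeR adjusted p = 3.7e-08) below that level, with 84 counts against 2, a ratio of 47.6 with an interval of 12.8 to 399, and reads cannot be assigned to either copy with certainty. The homeobox gene MEOX1 (chromosome 17, 43640389 to 43661922) rose 8.72-fold (3.12 ± 0.15, edgeR adjusted p = 3.8e-14), from 1.25 ± 0.398 CPM to 11.1 ± 1.30 CPM (SD, n = 3 each). The others were CEACAM6, a cell adhesion molecule (4.95-fold), the acute phase protein SAA1 (4.7-fold), the GABA receptor subunit GABRP (4.64-fold), the ammonium transporter RHCG (4.39-fold), the cytokine IL1B (4.23-fold), the chemokine CXCL1 (4.23-fold), the Dickkopf receptor KREMEN2 (4.22-fold) and keratin KRT79 (4.13-fold), with edgeR adjusted p from 2.2e-23 to 4.2e-06. RHCG was the most abundant of them, at 524 ± 29.3 CPM against 119 ± 13.5 CPM.

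The largest fall was that of OLR1 (chromosome 12, 10158301 to 10172138), the receptor for oxidized low-density lipoprotein, which was 5.94-fold lower (-2.57 ± 0.14, edgeR adjusted p = 4.8e-15; 1.25 ± 0.120 CPM against 7.47 ± 0.219 CPM). Loricrin (LOR, chromosome 1, 153259687 to 153262124), a main protein of the cornified envelope, was 3.83-fold lower (23.3 ± 4.41 CPM against 89.4 ± 12.1 CPM; edgeR adjusted p = 0.0013), and IGFBP3 was 3.63-fold lower (28.5 ± 2.25 CPM against 103 ± 5.9 CPM; edgeR adjusted p = 1.2e-18). The remaining genes with the largest falls were ECM2 (4.19-fold), BEST2 (4.1-fold), LAMP3 (3.99-fold), the estrogen sulfotransferase SULT1E1 (3.96-fold), the monooxygenase FMO2 (3.81-fold), SYNPO2 (3.33-fold) and the cytochrome P450 enzyme CYP1B1 (3.2-fold), with edgeR adjusted p from 6.2e-14 to 3.8e-06.

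**Figure D2:**
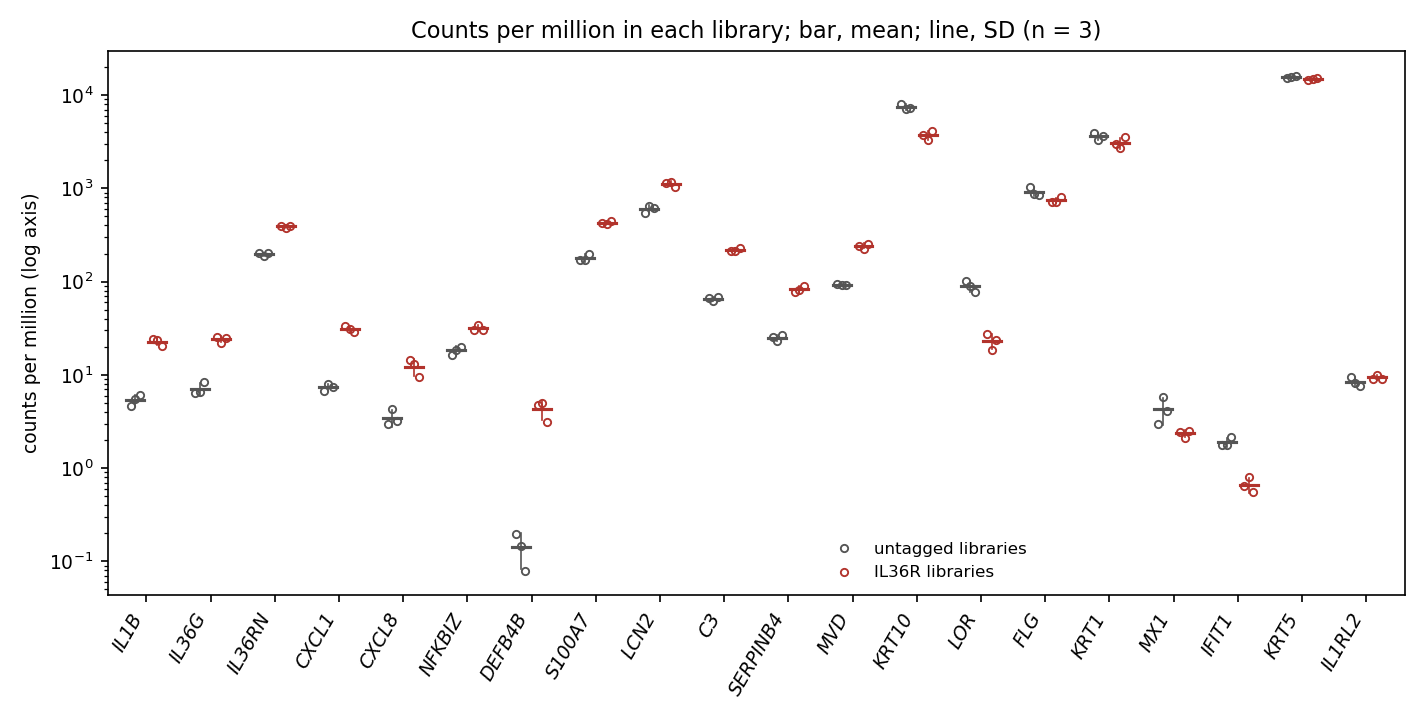
CPM (vertical log axis) of 20 named genes in each library. Open circles are libraries (grey, untagged; red, IL36R), bars are means and lines SD (n = 3 each); IL1B is at 22.7 ± 1.96 CPM against 5.39 ± 0.741 CPM and KRT10 at 3709 ± 415 CPM against 7468 ± 564 CPM (IL36R first), while IL1RL2 overlaps between the groups.

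Transcripts of the IL-1 family moved in both directions. IL1B (chromosome 2, 112829751 to 112836816) rose 4.23-fold (2.08 ± 0.091, edgeR adjusted p = 3.4e-16), and IL36G (chromosome 2, 112973203 to 112985658), which encodes IL-36γ itself, rose 3.44-fold (1.78 ± 0.086, edgeR adjusted p = 1.1e-14; 24.3 ± 1.82 CPM against 7.1 ± 1.08 CPM). The gene for the IL-36 receptor antagonist, IL36RN, rose 1.99-fold from 197 ± 7.08 CPM to 391 ± 10.1 CPM (edgeR adjusted p = 2.9e-18), and IL1F10 rose 2.94-fold. IL1RL2, which encodes a chain of the IL-36 receptor and not the whole of it, was not called (0.13 ± 0.093, edgeR adjusted p = 0.25, 9.37 ± 0.613 CPM against 8.47 ± 0.979 CPM). The gene for its other chain, IL1RAP, which other receptors of the family share, was lower (-0.38 ± 0.050, edgeR adjusted p = 2.6e-07). Receptor genes IL1RL1 (-1.22 ± 0.27) and IL18R1 (-0.84 ± 0.19) and the ligand gene IL18 (-0.57 ± 0.039) were also lower, and the receptor gene SIGIRR (0.75 ± 0.18) was higher. The list of IL-1 family ligands and receptors had 7 of 18 tested members higher and 5 lower (8 and 7 adjusted over the list alone) and was not called by camera (camera adjusted p = 0.41; median log2 fold change 0.10).

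The list of chemokines and cytokines had 12 of 22 tested members higher and 3 lower (12 and 3 adjusted over the list alone) and was called higher (camera adjusted p = 0.032, and adjusted p = 0.52 with an estimated correlation). CXCL1 (2.08 ± 0.075, edgeR adjusted p = 4.6e-19), CXCL6 (2.90 ± 0.30) and CXCL8 (1.81 ± 0.20, edgeR adjusted p = 1.5e-04), which attract neutrophils, rose, and so did CXCL16 (0.37 ± 0.047). The related genes CXCL2 (-0.0099 ± 0.23), CXCL3 (0.55 ± 0.37) and CXCL5 (0.74 ± 0.36) were not called, with edgeR adjusted p of 0.98, 0.23 and 0.097. TNF (1.32 ± 0.17) and IL23A (2.29-fold) were also higher, and the homeostatic skin chemokine CXCL14 was 2.63-fold lower (-1.39 ± 0.057, edgeR adjusted p = 1.3e-10). CCL20 was not called (0.34 ± 0.26, edgeR adjusted p = 0.30), although it passed without IL36R replicate 12 (log2 fold change 0.62, edgeR adjusted p = 0.018, in a range of 0.018 to 0.79 over the alternatives). IL17C was below the expression filter with 13 counts against 7, a ratio of 2.1 with a counting interval of 0.78 to 6.22, so a difference was not detectable at this depth. The call on this list was lost with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.096), without IL36R replicate 11 (0.065) and without untagged replicate 1 (0.051).

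Genes of the NF-κB pathway and its feedback had 15 of 23 tested members higher and 1 lower (15 and 1 adjusted over the list alone), and the list was called higher (camera adjusted p = 2.0e-04, and adjusted p = 0.41 with an estimated correlation). The ribonuclease ZC3H12A (1.48 ± 0.054), the kinase IRAK2 (1.22 ± 0.058), the inhibitor NFKBIA (0.88 ± 0.046), BIRC3 (1.34 ± 0.088) and NFKBIZ (0.80 ± 0.069, edgeR adjusted p = 6.7e-10), a nuclear co-regulator, were higher, and TNFAIP8 (-0.32 ± 0.068) was lower. The NF-κB subunit genes NFKB1 (0.09 ± 0.052) and RELA (-0.06 ± 0.038) were not called.

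Antimicrobial protein genes had 16 of 18 tested members higher (16 adjusted over the list alone), the other 2 being uncalled, and a median log2 fold change of 0.80 (camera adjusted p = 1.2e-07, and adjusted p = 0.16 with an estimated correlation). Besides the β-defensin 2 genes, S100A7 rose 2.38-fold (429 ± 15.7 CPM against 181 ± 16.9 CPM; edgeR adjusted p = 4.6e-10), LCN2 1.85-fold (1117 ± 69.0 CPM against 605 ± 56.1 CPM; edgeR adjusted p = 3.8e-05), PI3 1.84-fold, S100A9 1.64-fold and RNASE7 1.6-fold. PI3, which encodes the elastase inhibitor elafin, was among the abundant transcripts at 6252 ± 186 CPM against 3405 ± 216 CPM. Complement and acute phase genes had 8 of 13 tested members higher (10 adjusted over the list alone) and a median of 0.69 (camera adjusted p = 3.0e-04, and adjusted p = 0.17 with an estimated correlation). C3, the central complement component, rose 3.35-fold (1.75 ± 0.045, edgeR adjusted p = 7.4e-22), SAA2 4.11-fold and the complement inhibitor CD59 1.28-fold. Which copy the reads came from is uncertain for near-identical genes such as SAA1 and SAA2, SERPINB3 and SERPINB4, S100A7 and S100A7A, and the SPRR2, LCE3 and HLA genes. Of MHC class I and antigen processing genes, 10 of 16 were higher (10 adjusted over the list alone; camera adjusted p = 0.0015, and adjusted p = 0.43 with an estimated correlation), with TAPBP (0.61 ± 0.037), HLA-C (0.53 ± 0.039), B2M (0.32 ± 0.037) and HLA-B (0.77 ± 0.059) as examples.

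Type I interferon response genes did not move together. The list had 8 of 30 tested members higher and 6 lower (8 and 6 adjusted over the list alone), with a median log2 fold change of -0.04. Neither direction was called: camera placed the list lower (adjusted p = 0.82) and fry higher (adjusted p = 0.84). IFIT1 (-1.52 ± 0.24, edgeR adjusted p = 3.9e-06), MX1 (-0.84 ± 0.22, edgeR adjusted p = 0.0078) and SAMD9 (-0.46 ± 0.041) were lower. DDX58, which encodes the RNA sensor RIG-I (0.63 ± 0.062), OAS3 (0.49 ± 0.051) and ISG20 (0.57 ± 0.082) were higher. IFIT1 was expressed at a low level, 0.664 ± 0.123 CPM against 1.9 ± 0.212 CPM and 48 against 157 counts. CXCL10 was not called (-0.52 ± 0.31, edgeR adjusted p = 0.17; 37 against 60 counts). The list of virus sensing and herpesvirus entry genes had 10 of 22 tested members higher and 4 lower (11 and 4 adjusted over the list alone) and was not called by camera (camera adjusted p = 0.092), but it passed without IL36R replicate 10 (adjusted p = 0.048). TMEM173, which encodes the adaptor STING, rose 1.98-fold and NECTIN1, an entry receptor of herpes simplex virus, 1.48-fold (404 ± 23.7 CPM against 273 ± 3.06 CPM; edgeR adjusted p = 2.0e-12). SDC1 was higher (0.32 ± 0.038), and the DNA sensor IFI16 was lower (-0.63 ± 0.040). The list of type 2 response genes had 4 of 8 tested members higher and 3 lower (4 and 3 adjusted over the list alone). SOCS1 (0.96 ± 0.14) and CISH (0.77 ± 0.11) rose, and CA2 (-0.76 ± 0.045) and TSLP (-2.42 ± 0.32; 0.266 ± 0.114 CPM against 1.49 ± 0.277 CPM) fell. Its median was 0.08 and its mean -0.27, camera gave the direction up and fry down, and neither called it (adjusted p = 0.91 and 0.9997).

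**Figure D3:**
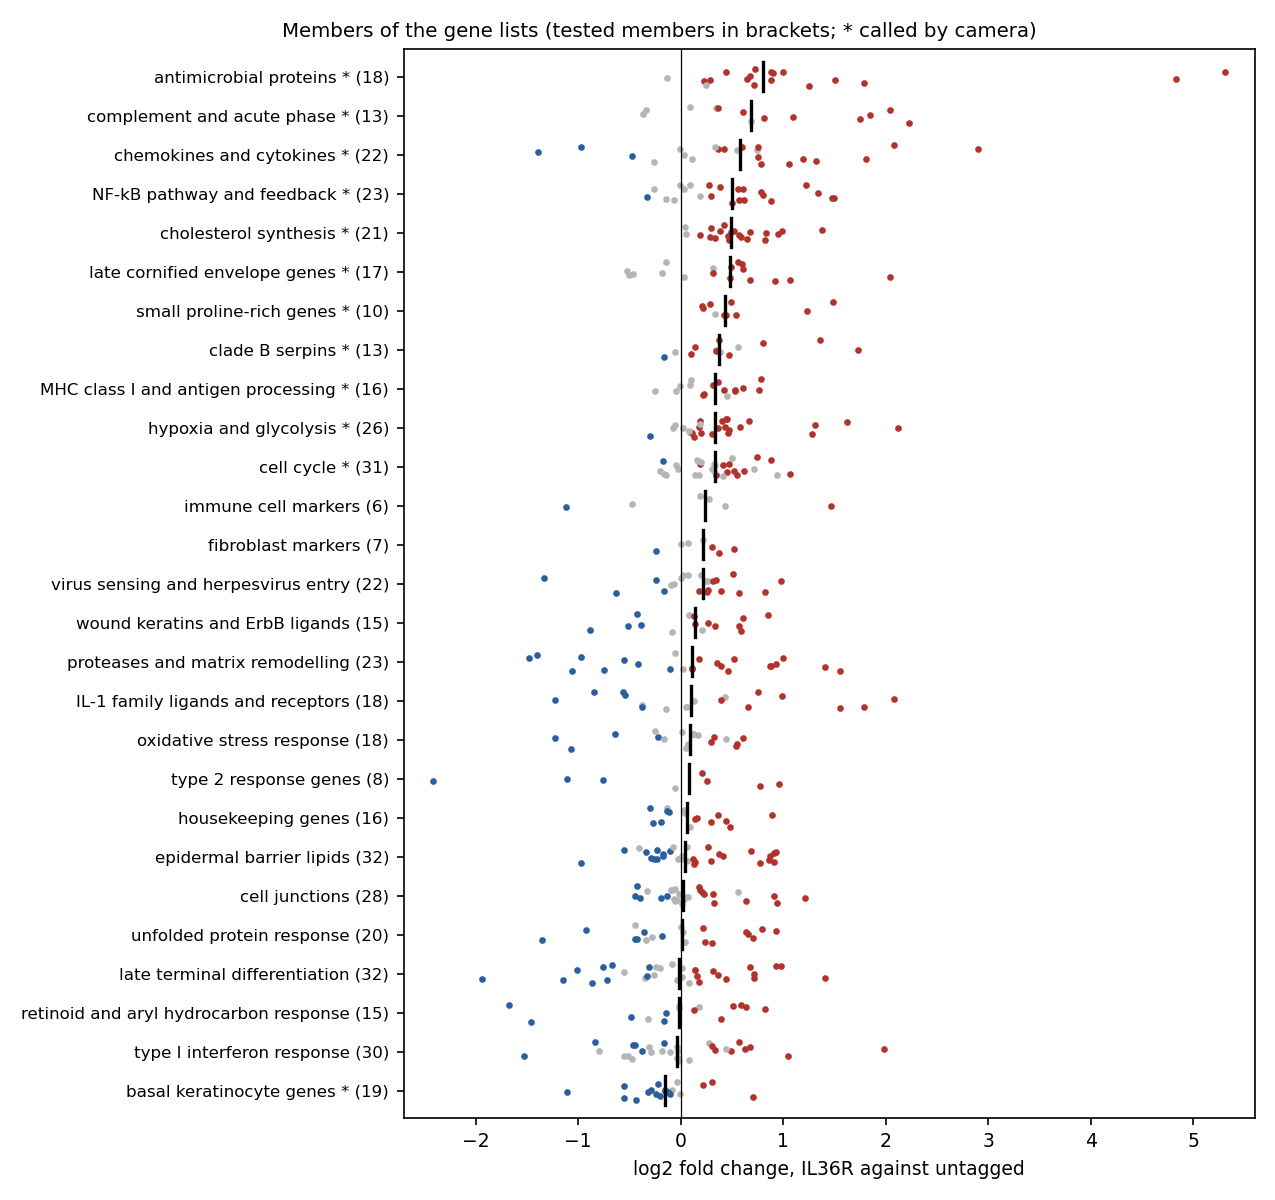
Log2 fold change (horizontal axis, IL36R against untagged) of the tested members of the 27 lists that were tested, ordered by median. Each point is a gene (red, called higher; blue, called lower; grey, not called), black bars are medians, brackets give tested members and asterisks mark the 11 lists called higher and the 1 called lower by camera at the preset correlation; medians run from -0.16 for basal keratinocyte genes to 0.80 for antimicrobial proteins.

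Late differentiation genes split in direction. Of 32 late terminal differentiation genes 12 were higher and 9 lower (13 and 9 adjusted over the list alone; camera adjusted p = 0.91). Their median was -0.015, and no direction was called by camera or fry. Keratin KRT10, the type I keratin of suprabasal cells, was 2.01-fold lower (3709 ± 415 CPM against 7468 ± 564 CPM; edgeR adjusted p = 0.0012), as were BLMH (-0.86 ± 0.076) and CALML3 (-0.67 ± 0.072). Its partner KRT1 was not called (-0.24 ± 0.13, edgeR adjusted p = 0.21). It passed as lower with limma-voom, without robust estimation and without IL36R replicate 12, with an adjusted p of 0.0095 to 0.44 over the alternatives. PADI1, a peptidylarginine deiminase, rose 2.66-fold and involucrin (IVL) 1.24-fold (2082 ± 78.3 CPM against 1676 ± 105 CPM; edgeR adjusted p = 8.6e-07). Filaggrin (FLG) lay at the threshold (-0.30 ± 0.096, edgeR adjusted p = 0.0496; 746 ± 50.8 CPM against 921 ± 102 CPM). That call was lost without IL36R replicate 10 or 11, without mitochondrial genes and after removal of a length trend, with adjusted p between 0.00054 and 0.11 over the alternatives.

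Small proline-rich genes, whose products are cross-linked into the cornified envelope, had 9 of 10 members higher (10 adjusted over the list alone; camera adjusted p = 2.0e-04, and adjusted p = 0.16 with an estimated correlation), among them SPRR2F (1.49 ± 0.13), SPRR2E (0.49 ± 0.039), SPRR2D (0.44 ± 0.041) and SPRR1B (0.29 ± 0.039). Late cornified envelope genes had 10 of 17 tested members higher (10 adjusted over the list alone; camera adjusted p = 0.026, and adjusted p = 0.70 with an estimated correlation), and this call was lost without untagged replicate 3 (adjusted p = 0.13). LCE2B (0.61 ± 0.042), LCE2C (0.92 ± 0.061), LCE2D (0.68 ± 0.062), LCE3E (0.60 ± 0.042) and LCE3A (2.04 ± 0.27, edgeR adjusted p = 3.4e-07; 146 against 40 counts) rose. The 8 tested LCE2 and LCE3 genes were all called higher, whereas the 6 LCE1 genes had log2 fold changes of -0.52 to 0.037 and edgeR adjusted p of 0.069 to 0.67. The subfamilies were singled out after their values were seen.

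Many of these genes lie in the epidermal differentiation complex, a cluster on chromosome 1 taken here from S100A10 to S100A1 (151982915 to 153632039 on GRCh38, 1.65 Mb), a region chosen after the values were seen. Of its 60 tested genes 40 were higher and 5 lower. The 5 were TCHHL1 (-0.82 ± 0.16), TCHH (-1.14 ± 0.12), FLG, LOR and S100A14 (-0.24 ± 0.036). Among S100 genes of the region 12 of 14 were higher.

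**Figure D4:**
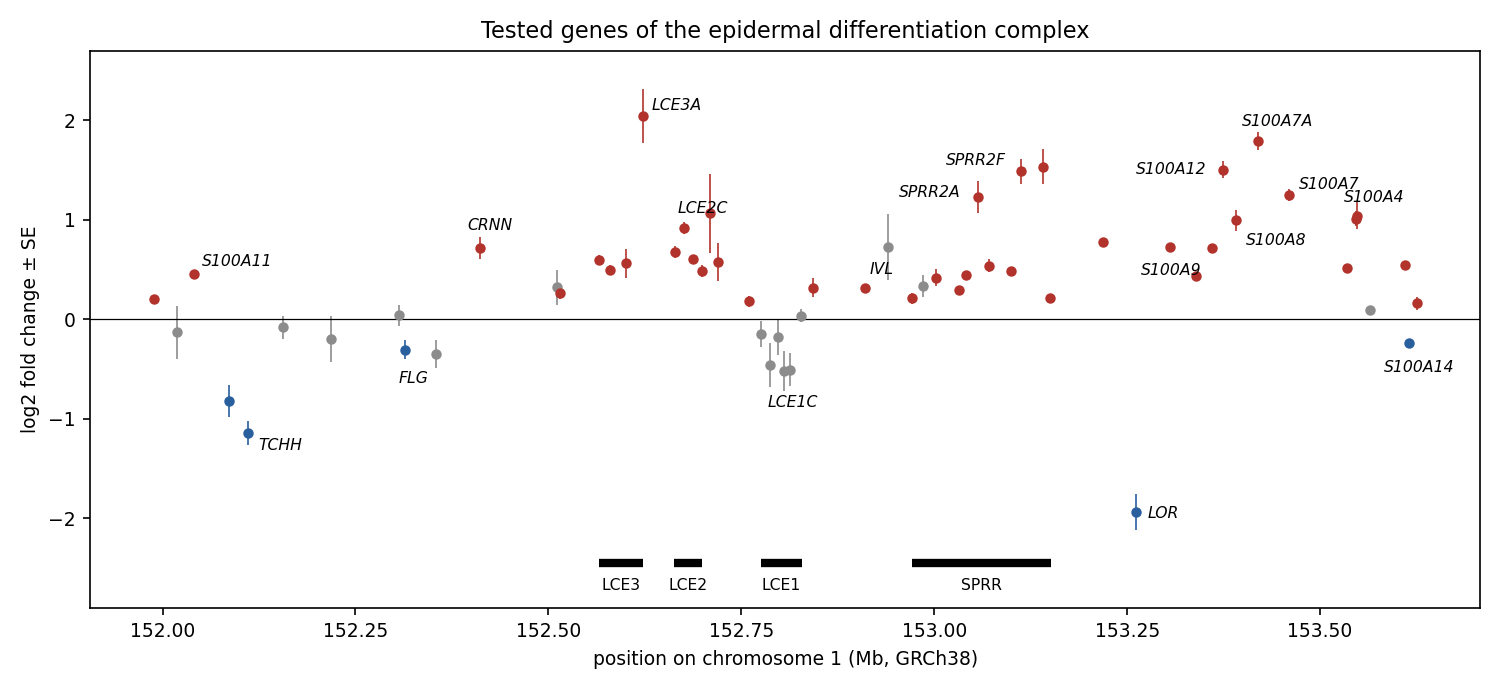
Log2 fold change ± SE (vertical axis, IL36R against untagged) of the 60 tested genes of the epidermal differentiation complex against their position on chromosome 1 (Mb, GRCh38). Red points were called higher (40 genes), blue lower (5) and grey not called, and black bars span the LCE and SPRR families; the LCE3 and LCE2 genes lie above 0 and the adjacent LCE1 genes between -0.52 and 0.037.

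Cholesterol synthesis genes had 19 of 21 members higher (19 adjusted over the list alone; camera adjusted p = 3.4e-10, and adjusted p = 0.17 with an estimated correlation). MVD, the mevalonate diphosphate decarboxylase, rose 2.61-fold (1.38 ± 0.043, edgeR adjusted p = 1.7e-20), the HMG-CoA synthase HMGCS1 1.93-fold (507 ± 19.9 CPM against 263 ± 5.74 CPM), and lanosterol synthase LSS 1.78-fold. The regulator gene SREBF2 (0.04 ± 0.036, edgeR adjusted p = 0.37) was not called. Epidermal barrier lipid genes moved both ways, with 14 of 32 tested members higher and 10 lower (14 and 11 adjusted over the list alone) and no camera call (camera adjusted p = 0.41). ALOX12B (0.69 ± 0.041), SMPD1 (0.78 ± 0.046), LIPK (0.86 ± 0.065) and ELOVL1 (0.41 ± 0.038) were higher, and ELOVL3 (-0.97 ± 0.29) was lower. Hypoxia and glycolysis genes had 20 of 26 tested members higher and 1 lower (21 and 1 adjusted over the list alone) and were called higher (camera adjusted p = 4.2e-05, and adjusted p = 0.33 with an estimated correlation), including ALDOC (3.08-fold), PGAM1 (1.49-fold), ALDOA (1.38-fold) and HIF1A (1.37-fold).

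Basal keratinocyte genes were the 1 list called lower, with 3 of 19 tested members higher and 13 lower (3 and 14 adjusted over the list alone) and a median of -0.16 (camera adjusted p = 0.0092, and adjusted p = 0.17 with an estimated correlation). DST (-0.56 ± 0.039), CAV1 (-0.55 ± 0.036) and TP63 (-0.44 ± 0.038), the transcription factor of the basal layer, fell, while the basal keratin KRT15 rose (0.71 ± 0.039). Integrins of this list went both ways, with ITGB4 (-0.32 ± 0.036), ITGA3 (-0.24 ± 0.037) and ITGB1 (-0.22 ± 0.037) lower and ITGA2 (0.31 ± 0.038) higher. KRT5 was not called in the main test (-0.08 ± 0.037, edgeR adjusted p = 0.062; 14859 ± 396 CPM against 15743 ± 442 CPM), and its adjusted p ran from 0.00020 to 0.31 over the alternatives. Cell cycle genes had 11 of 31 tested members higher and 1 lower (7 and 1 adjusted over the list alone) and were called higher (camera adjusted p = 0.012, and adjusted p = 0.17 with an estimated correlation). CDC6 (0.89 ± 0.13), TK1 (1.06 ± 0.18), MCM5 (0.34 ± 0.087) and CCNB1 (0.47 ± 0.12) rose (CDC6 at 5.28 ± 0.153 CPM against 2.87 ± 0.435 CPM), and PCNA was lower (-0.17 ± 0.060). MKI67, a proliferation marker, missed the threshold (0.34 ± 0.15, edgeR adjusted p = 0.051; 3.39 ± 0.110 CPM against 2.67 ± 0.319 CPM), with an adjusted p of 0.015 to 0.16 over the alternatives. Clade B serpins, inhibitors of proteases, had 8 of 13 tested members higher and 1 lower (9 and 1 adjusted over the list alone) and were called higher (camera adjusted p = 0.0092, and adjusted p = 0.17 with an estimated correlation): SERPINB4 rose 3.33-fold (83.2 ± 6.14 CPM against 25.0 ± 1.81 CPM), SERPINB1 1.75-fold, SERPINB3 1.39-fold and SERPINB13 1.27-fold.

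The other lists were not called by camera. Wound keratins and ErbB ligands had 8 of 15 tested members higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.41). KRT16 (0.34 ± 0.036, edgeR adjusted p = 6.2e-09), TGFA (0.61 ± 0.043) and SPHK1 (0.57 ± 0.045) were higher, and EGFR (-0.39 ± 0.037) was lower. Proteases and matrix remodelling genes had 13 of 23 tested members higher and 8 lower (13 and 8 adjusted over the list alone); camera gave the direction up (adjusted p = 0.50) and fry down (adjusted p = 0.84). PLAU rose 1.84-fold, and SERPINE2 (1.96-fold), MMP1 (2.8-fold) and ADAMTS1 (1.68-fold) fell. Cell junction genes had 10 of 28 tested members higher and 5 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.50), with TJP3 (1.22 ± 0.074) and CGN (0.94 ± 0.062) higher and GJA1 (-0.45 ± 0.041) and DSC3 (-0.42 ± 0.039) lower. Their median, 0.021, turned negative (-0.00086) when libraries were scaled by total counts, and fry called the list higher (adjusted p = 0.038). Oxidative stress genes had 6 of 18 tested members higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.59), with HMOX1 (0.61 ± 0.040), ME1 (0.55 ± 0.039) and DUOXA1 (0.54 ± 0.042) higher and DUOX2 (-1.07 ± 0.075) lower. Their median was 0.094, their mean -0.016, and both tests gave the direction up (fry adjusted p = 0.031).

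Unfolded protein response genes had 8 of 20 tested members higher and 6 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.82). The chaperone genes MANF (0.93 ± 0.046), PDIA4 (0.71 ± 0.041), HSP90B1 (0.64 ± 0.040) and CRELD2 (0.80 ± 0.068) rose, and ASNS (-1.35 ± 0.15) and ATF3 (-0.92 ± 0.076) fell. The median of this list was 0.015, or -0.0078 with total counts, and its mean -0.0093, with the direction up in camera and fry. Retinoid and aryl hydrocarbon response genes had 6 of 15 tested members higher and 5 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.91). CRABP2 (0.82 ± 0.041) rose and NFE2L2 (-0.49 ± 0.040) fell. Their median was -0.020 and their mean -0.068, with the direction up in camera and fry. Housekeeping genes had 7 of 16 tested members higher and 5 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.41), with TFRC (0.89 ± 0.057), ACTB (0.48 ± 0.040), PGK1 (0.44 ± 0.043) and CYC1 (0.36 ± 0.040) higher (fry adjusted p = 0.0016). By fry 18 lists were higher and 1 lower, among them, beyond those called by camera, IL-1 family (adjusted p = 5.4e-04), virus sensing (0.0059), barrier lipid (0.0036) and fibroblast marker genes (0.0079). With an estimated correlation 0 of the 12 lists called by camera kept their call.

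Markers of other cell types were mostly low. Of 12 melanocyte markers 9 were below the expression filter, the highest of them at 0.144 CPM, while PMEL (4.32 ± 0.309 CPM against 1.89 ± 0.229 CPM; edgeR adjusted p = 1.4e-07) and GPR143 (1.85 ± 0.255 CPM against 1.3 ± 0.199 CPM; edgeR adjusted p = 0.035) were higher and MITF (18.7 ± 0.602 CPM against 28.8 ± 1.03 CPM; edgeR adjusted p = 5.3e-10) was lower. The GPR143 call was lost under several alternatives, with an adjusted p of up to 0.15. Of 12 endothelial and Merkel cell markers 4 were tested. KRT8 rose 2.63-fold (684 ± 58.0 CPM against 259.8 ± 33.0 CPM; edgeR adjusted p = 8.6e-04), KRT18 1.39-fold (543 ± 16.2 CPM against 391 ± 9.28 CPM; edgeR adjusted p = 1.7e-11) and VWF 1.71-fold (5.16 ± 0.796 CPM against 3.02 ± 0.443 CPM; edgeR adjusted p = 3.7e-05). TEK was lower (1.42 ± 0.359 CPM against 2.33 ± 0.624 CPM; edgeR adjusted p = 0.0088), a call lost when any of 3 libraries was left out (highest adjusted p = 0.058). These lists had too few tested members for a set test. Of the 20 immune cell markers 6 were tested: CD14 was higher (0.939 ± 0.162 CPM against 0.340 ± 0.151 CPM), ITGAM was lower (0.891 ± 0.192 CPM against 1.97 ± 0.295 CPM). CD3E, CD74, CSF1R and ITGAX were not called, with edgeR adjusted p from 0.10 to 0.30 (camera adjusted p = 0.67 for the list). The pan-leukocyte gene PTPRC had no count in any library. Among markers below the filter, CD68 (12 against 2 counts) and CD163 (8 against 3) were higher in IL36R. FCGR3A (5 against 6), CD4 (11 against 13) and LYZ (0 against 2) were not. Of 13 fibroblast markers 7 were tested: COL5A1 (0.52 ± 0.057), COL1A1 (0.31 ± 0.052) and THY1 (0.38 ± 0.10) were higher. FBLN1 (-0.24 ± 0.073) was lower except without untagged replicate 1 (adjusted p = 0.072), and COL1A2, VIM and FAP were not called, with edgeR adjusted p of 0.15, 0.20 and 0.99 (camera adjusted p = 0.23 for the list).

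Mitochondrially encoded RNA made up 2.90 ± 0.17% of counts in IL36R and 3.98 ± 0.48% in untagged libraries (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible). The 10 most abundant genes of each library held 10.96 ± 0.12% and 10.75 ± 0.24% of its counts (exact permutation p = 0.30).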

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

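The 4 gene counts stayed within 1.5 times their values under DESeq2 size factors, upper-quartile factors, total counts, the DESeq2 Wald test, limma-voom, no filter, no mitochondrial genes, no robust estimation and each left-out library, and no gene called in both settings changed direction. The DESeq2 Wald test shared the fewest of the 7428 calls among these, 5931. Leaving out 1 library gave 3390 to 3553 genes higher, 3184 to 3348 lower, 349 to 416 at least 2-fold higher, 229 to 263 at least 2-fold lower, 10 to 12 lists higher and 1 list lower. At an adjusted p below 0.01, 2971 genes were higher and 2758 lower. Tested against a 1.5-fold change 392 were higher and 182 lower, since most changes are smaller. With at least 1 CPM in at least 3 libraries, which tests fewer genes, 233 genes were at least 2-fold higher and 129 lower. Of the added alternatives, chosen after seeing the data, GC correction gave 3502 and 3475, length correction 3711 and 3639, and thinning 3544 and 3410. The medians of all genes moved by at most 0.023 between scalings. With a correlation estimated per list, camera called 0 lists higher and 0 lower in place of 11 and 1 (6 and 1 at an unadjusted p under 0.05), with adjusted p of 0.16 to 0.70 for the 12. The estimate was below the preset 0.01 for small proline-rich (-0.017), basal keratinocyte (0.0075), clade B serpin (-0.032) and cell cycle genes (0.0084). It was above 0.01 for the others of the 12. A lost call is thus not by itself a sign of correlation between members, since that form of camera also has fewer degrees of freedom. Fry called 18 higher, and it does not compare a list with other genes. CameraPR on ranks gave 11 and 1. Of 138 called named genes, 134 kept their call and direction under every alternative that tests for any change at the 0.05 threshold. FLG, GPR143, FBLN1 and TEK did not, and the cause was not tested. Against a 1.5-fold change 62 lost their call. Of 13 uncalled ones 7 passed under at least 1.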

Other observations

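The gene groups in this part, the test of mitochondrial rRNA and the tests of other cell types were chosen after the data were seen; the tests of other splits, GC content, transcript length, depth, single libraries and nuclear copies were set before their results were seen. Gene values in brackets are log2 fold changes ± SE. Of a group of ATF4 and amino acid response genes, which holds enzymes, transporters and tRNA ligases for amino acids along with other genes of that stress response, most were lower in the IL36R libraries: 28 of 34 fell and 1 rose, with a median log2 fold change of -0.57 (camera adjusted p = 3.5e-10, and adjusted p = 0.23 with an estimated correlation). Asparagine synthetase ASNS (-1.35 ± 0.15), the serine pathway enzymes PSAT1 (-1.31 ± 0.16) and PHGDH (-0.96 ± 0.042), the mitochondrial folate enzymes ALDH1L2 (-1.62 ± 0.17) and MTHFD2 (-0.86 ± 0.085), the transporters SLC7A11 (-1.23 ± 0.14) and SLC7A5 (-1.06 ± 0.11) and ATF4 itself (-0.36 ± 0.051) fell. Fatty acid synthesis genes went the other way, with 13 of 17 higher and 3 lower (camera adjusted p = 7.2e-05, and adjusted p = 0.075 with an estimated correlation), among them FADS2 (1.55 ± 0.048), ELOVL6 (1.06 ± 0.047), ACLY (0.92 ± 0.042), SCD (0.80 ± 0.040) and FASN (0.65 ± 0.041).

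Of 79 cytosolic ribosomal protein genes 58 fell, with a median of -0.15 (camera adjusted p = 1.3e-09, and adjusted p = 0.19 with an estimated correlation), and the median stayed between -0.17 and -0.15 under all 4 scalings. Of 37 nuclear genes for subunits of respiratory complex I, 27 rose and 2 fell, with a median of 0.20 (camera adjusted p = 2.6e-05, and adjusted p = 0.081 with an estimated correlation) that lay between 0.18 and 0.20 over the 4 scalings. Scaling shifts all genes of a library alike, so the 4 scalings could hardly move either median. Of 423 zinc finger genes with ZNF names 97 (22.9%) were lower and 45 (10.6%) higher, against 23.8% and 24.9% of all tested genes. Camera gave the direction down (camera adjusted p = 0.025, and adjusted p = 0.081 with an estimated correlation), with a median log2 fold change of -0.073. A smaller share of this group was called and the shares were not tested. They do not show whether the group lacks higher genes or moved down as a whole.

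Of 13 mitochondrially encoded mRNAs 8 were lower, with a median log2 fold change of -0.60 (camera adjusted p = 2.5e-05, and adjusted p = 0.23 with an estimated correlation). MT-CYB fell most (-1.24 ± 0.11), and MT-ND6 changed least and was not called (-0.13 ± 0.22). A loss of all mitochondrial RNA is argued against by the rRNAs, MT-RNR1 (-0.14 ± 0.12) and MT-RNR2 (-0.01 ± 0.10), the nearer of which lay 2.7 standard errors above the median mRNA. That standard error combines the SE of the rRNA with the median SE of single mRNAs as if independent. Both come from the same libraries, so the distance is a rough scale and not a test. No single library set the fall, since the median stayed at -0.54 or below without any 1 of them. The 11 tested nuclear copies of the mitochondrial genome did not rise. Their median also fell (-0.74, with a median SE of 0.19), with 5 called lower and 0 higher. Reads assigned to a copy may themselves come from mitochondrial RNA, and MTND1P23 (-1.02 ± 0.12), for example, moved like MT-ND1 (-1.05 ± 0.11). Such copies would follow their parent genes, so they say little about a shift of reads. A lower level of mitochondrial mRNA in the IL36R wells, or a different share of these mRNAs kept by poly(A) selection, may account for the fall, and neither was tested.

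The call of 48.8% of tested genes may seem wide for wells of 1 donor. Removing a GC trend per library left 6977 called genes, removing a transcript length trend left 7350 and thinning every library to the smallest total left 6954, against 7428, so none of these accounts for the count as a whole. Of the earlier calls 5863, 6693 and 6759 were shared in the same direction. With a common biological variation between wells of 4.03%, small differences pass the test. A difference in how the wells of the groups were handled is confounded with the tag and stays open beside a response to the treatment the tag stands for.

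Some genes also listed as markers of other cell types were higher in IL36R, and PMEL, KRT8 with KRT18, and VWF were tested for a source in other cells. GPR143, CD14, COL5A1, COL1A1 and THY1 also rose, and a source of CD14 in immune cells was not tested. COL5A1, COL1A1 and THY1 are fibroblast markers, but the fibroblast genes COL3A1 (4 against 3 counts), LUM (3 against 3) and DCN (9 against 33) stayed near 0. COL6A3 (9 against 11) and PDGFRB (5 against 8) were also low, and PDGFRA (21 against 18) was slightly higher. Most of these low counts speak against fibroblasts, although PDGFRA does not and no bound was set for them. Merkel cells are argued against for KRT8 and KRT18, since the summed rise of the 4 other Merkel cell markers was at most 0.021% of theirs at the upper end of its 95% counting interval. For PMEL the 10 other melanocyte markers that were not called lower rose by up to 44.7% of its rise, past the bound of 10%. Most of this is GPR143 (136 against 107 counts), whose own call is unstable, while MLANA and TYRP1 had 1 count in each group and TYR and SOX10 had 0, which speaks against melanocytes without meeting the bound. For VWF the 4 such endothelial markers rose by up to 11.5%, mainly through CLDN5 (10 against 2 counts), while PECAM1 (2 against 3), CDH5 (1 against 1) and KDR (3 against 2) did not, so endothelial cells are left open on few counts. The choice of markers was changed after results were seen. With all other markers, used first, the summed change was negative for melanocytes (-9.50 CPM) and endothelial cells (-0.78 CPM) through MITF and TEK, which could hide a rise. With only those below the filter melanocytes came to 9.59%, but GPR143 was left out. Leaving out only those that fell, as above, depends on the outcome and favours a rise, so this test decides for neither cell type.

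The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split by tag gave 3799 genes higher, 3629 lower, 350 at least 2-fold higher and 223 at least 2-fold lower, and the highest count in any of the other 9 splits was 0 in edgeR for each of these. Each of the other 9 splits mixes tagged and untagged libraries within its groups. The difference by tag then adds to the spread within groups and lowers the counts, so these splits are no baseline for chance. At an unadjusted p under 0.05 edgeR gave 8240 genes in the split by tag and at most 232 in another. In the list test the split by tag gave 11 lists higher and 1 lower, and the highest count of lists in 1 direction in another split was 7. As large a count was given by 1 of the 10 splits for the higher lists, the split by tag itself, and by 10 of 10 for the lower list. Camera at the preset correlation thus called lists in splits in which edgeR called no gene. Part of the difference by tag remains between the groups of these mixed splits, so such list calls are no measure of false calls.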
